A study of Mus musculus with 4 samples.

How the data were processed

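Footpads of C57BL/6 mouse embryos at embryonic day 16.5 were compared between wild-type animals and Tabby animals, which carry a mutation of the ectodysplasin gene Eda. There were 4 arrays, 2 wild-type and 2 Tabby, with replicate numbers 3 and 4 in both groups. Per the labels, the wild-type samples were male and the Tabby samples of mixed sex, so sex and genotype cannot be told apart. No label says that the samples came from separate animals or litters, so p-values measure only the spread between these samples, which may be technical.

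Each array was a 2-colour Agilent array of 60-base probes. Per the labels, Cy3 held footpad RNA and Cy5 held a reference pooled from cultured mouse cell lines, the same on every array, and lithium chloride precipitation was used on the footpad RNA against genomic DNA. Per the file headers, the deposited intensity values were read with Agilent Feature Extraction 9.5.1.1, and they comprise mean spot and median background signals and processed signals. The processed signals were background-subtracted and dye-normalized, per the file headers, and the deposited log10 ratio is that of processed Cy5 to processed Cy3. Its sign was turned here, so that a positive value means more footpad than reference signal. All 4 arrays lay on 1 slide, the wild-type samples at positions 1 and 2 and the Tabby samples at positions 3 and 4. Position on the slide and genotype therefore cannot be told apart.

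The authors' value table gives log10 values for 25164 probes. Its rows were matched to spots by feature number. The value plus the deposited log10 ratio was nearly the same on all 4 arrays, with a median range of 9.67e-05 and a largest range of 0.0774. That sum followed the probe's mean log10 processed Cy5 (r = 1.000 across probes). The table was first read as Cy3 intensity alone, because each column correlated with log10 processed Cy3 of its array (r from 0.998 to 0.999 across probes). That reading was dropped: differences between groups in the table followed the ratio (r = 0.996) more closely than Cy3 (r = 0.675). The table is therefore the footpad to reference ratio placed on the mean reference intensity, and it is no independent check of the processed signals. Column medians were 2.46 and 2.46 for wild-type replicates 3 and 4, and 2.45 and 2.46 for Tabby replicates 3 and 4, on the log10 scale. The rule by which the authors chose its probes stays unknown.

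With limma 3.58.1 in R 4.3.3, the mean and background signals were corrected by normexp with an offset of 50 and normalized within each array by loess, with control spots at weight 0. Control spots and spots flagged as outliers were then left out, which removed 12, 1, 3 and 3 spots besides the controls. Spots of 1 probe were averaged. Probes were tested if Cy3 was well above background on both arrays of at least 1 group. The Tabby minus wild-type difference of log2(Cy3/Cy5) was fitted with lmFit and eBayes and adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. Each channel was also fitted alone after normexp and quantile normalization.

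The test, the rule for named items and the alternatives for the count of calls and for named items were chosen before the data were examined, except the crossed pairing and the removal of GC content. The alternatives for unadjusted counts, for the telomere repeat and for the reference channel were also chosen afterwards. The test and the rule had been written for genes, but the files do not pair the probe IDs with gene names: 0 of 42006 IDs matched the gene table used, and every description was the same. Tests were therefore made per probe, and the 34 gene lists that had been fixed were not analysed here. The rule names, where fewer than 10 items pass, those with the smallest p in each direction whose Tabby arrays both lie beyond both wild-type arrays, with Cy3 well above background in the higher group. It was limited here to 2 probes per direction.

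The fit was tested on simulated data drawn with the fitted variances for the Tabby minus wild-type comparison of 28242 probes. With 200 probes changed 2-fold, 185 were recovered with 13 false calls, and with 200 changed 4-fold, 198 were recovered with 12 false calls. The simulation drew variances from the model that was then fitted and gave arrays of a group no structure of their own. It therefore describes a better case than these arrays. Recovery with fewer than 200 changed probes was not simulated.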

Results

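The study set out to find genes that depend on Eda, the ectodysplasin signal, while sweat glands form in the footpad, and these arrays cover embryos at E16.5. Footpad RNA of 2 wild-type and 2 Tabby samples was measured against a common cell line reference. Cy3 was well above background at 67.5% and 69.2% of the non-control spots for wild-type replicates 3 and 4, and at 67.9% and 65.8% for Tabby replicates 3 and 4. No spot was saturated. The number of arrays limits the precision.

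Footpads differed widely from the reference in both genotypes. Of 28242 probes tested, 891 were at least 8-fold higher in footpad than in reference RNA on all 4 arrays, and 277 were at least 8-fold lower on all 4. The arrays resembled each other closely, with 1 exception. Correlations of log2(Cy3/Cy5) across probes ran from 0.995 to 0.997 among wild-type replicate 4 and both Tabby arrays, and from 0.976 to 0.987 between wild-type replicate 3 and the others. Wild-type replicate 3 was over 2-fold above every other array at 129 probes, and wild-type replicate 4 at 0.

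No probe passed the threshold between Tabby and wild-type footpads. limma called 0 of 28242 probes at an adjusted p under 0.05, the smallest adjusted p being 0.113, while 3004 had an unadjusted p under 0.05, 1044 of them higher and 1960 lower in Tabby. That lean depended on the scaling, with 916 higher and 967 lower for processed signals, 1616 and 1676 for Cy3 alone, and 309 and 3349 for median centring. On Cy3 alone limma called 2 probes, and without wild-type replicate 3 it called 381, a fit that assumes the lone wild-type sample to vary like the Tabby samples. Without wild-type replicate 4 the same fit called 7250. For 97.8% of the probes the 95% interval of the change lay within 2-fold in either direction. These intervals hold for the ratio with the normexp offset of 50, and the spread between samples behind them may be technical. For Z00054739-1 the interval ran from -0.98 to -0.56. Its change was -1.27 with an offset of 16 and -2.58 with processed signals. Z00036698-1 also fell further with both, whereas Z00026015-1 and Z00028299-1 rose less or reversed. The intervals therefore do not exclude 2-fold changes under other processing. Changes of at least 2-fold in the ratio were measured at 36 probes, all of them lower in Tabby. Against wild-type replicate 3 only, the fall was at least 2-fold at 34 of these 36, and against wild-type replicate 4 only at 5. Wild-type replicate 3 was the higher wild-type array at 31 of them, and Z00036698-1 was not among these. Wild-type replicate 4 was also above both Tabby arrays at all 36, which were picked by their falls.

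The probe with the smallest p was Z00036698-1, which has the sequence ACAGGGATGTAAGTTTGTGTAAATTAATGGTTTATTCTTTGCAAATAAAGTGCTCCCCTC. Its log2(Cy3/Cy5) was 1.25 ± 0.14 (SD, n = 2) in wild-type and -0.27 ± 0.06 (SD, n = 2) in Tabby footpads. The difference was -1.53 with a standard error of 0.09 and a limma adjusted p of 0.113. In Cy3 alone it was -1.56, with a limma adjusted p of 0.0404, and in the reference channel -0.08, with a limma adjusted p of 0.828. Z00054739-1 was the second of the lower probes, at 0.99 ± 0.10 (SD, n = 2) in wild-type and 0.22 ± 0.09 (SD, n = 2) in Tabby footpads, a difference of -0.77 with a limma adjusted p of 0.439. Its Cy5 signal was well above background on 0 of the 4 arrays, so the size of its ratio rests in part on a dim reference signal. In Cy3 alone the difference was -0.61, with a limma adjusted p of 0.394, and in the reference channel it was 0.07. With Agilent's processed signals the ratio differed by -2.58, processed Cy3 by -1.94 and processed Cy5 by 0.65.

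Both higher probes were also higher on the Tabby arrays in the reference channel, which held the same RNA on every array. Z00026015-1 was at 5.11 ± 0.05 (SD, n = 2) in wild-type and 5.89 ± 0.03 (SD, n = 2) in Tabby footpads, a difference of 0.78 with a limma adjusted p of 0.439. It was higher by 0.996 in Cy3 alone, with a limma adjusted p of 0.0744, and by 0.30 in the reference channel, with a limma adjusted p of 0.0325. Z00028299-1 was at 1.53 ± 0.10 (SD, n = 2) in wild-type and 2.23 ± 0.03 (SD, n = 2) in Tabby footpads, a difference of 0.70 with a limma adjusted p of 0.439. It was higher by 1.19 in Cy3 alone, with a limma adjusted p of 0.0404, and by 0.51 in the reference channel, with a limma adjusted p of 0.000923. With Agilent's processed signals, the ratio of Z00026015-1 differed by -0.06 and that of Z00028299-1 by 0.06, while processed Cy3 was higher in Tabby by 1.16 and 1.55 and processed Cy5 by 1.23 and 1.49.

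**Figure D1:**
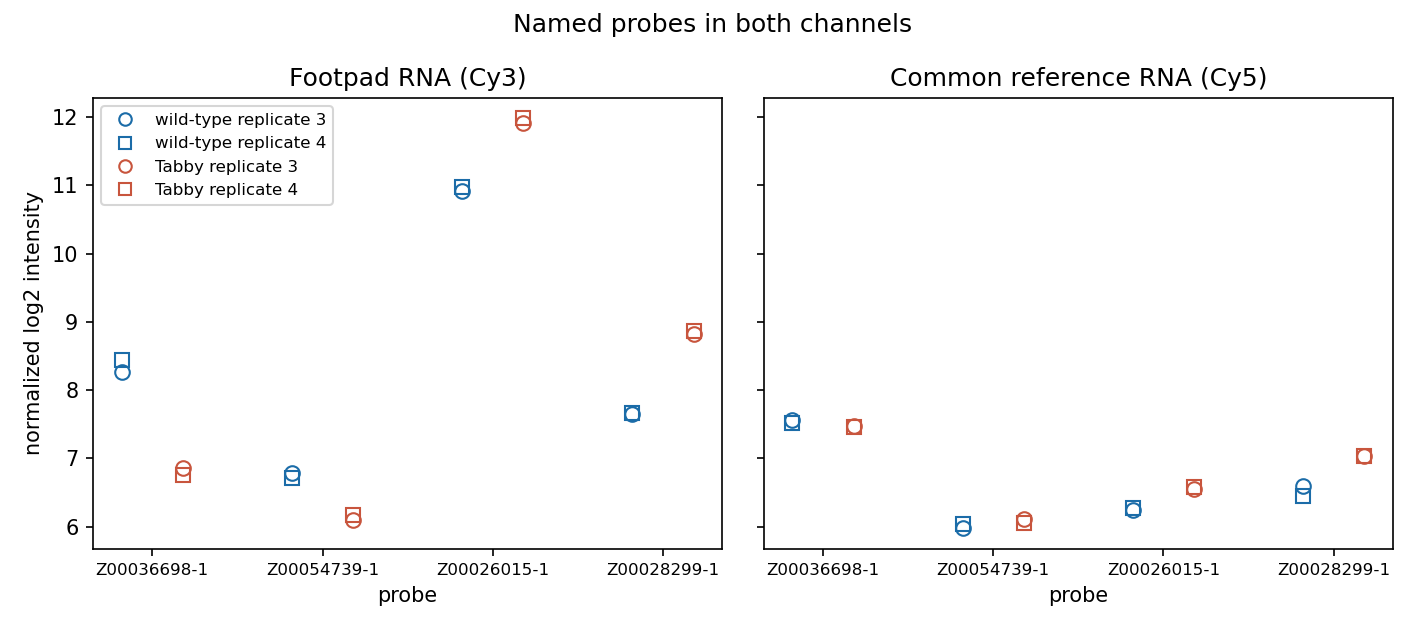
Normalized log2 intensity (vertical axis) of the 4 named probes (horizontal axis) in the footpad channel, left, and the reference channel, right, with 1 point per array and colours for the groups. Z00036698-1 differs by -1.56 in Cy3 and by -0.08 in Cy5, whereas Z00028299-1 differs by 1.19 in Cy3 and by 0.51 in Cy5.

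Sequences shared by the higher probes were counted as a description. Of the 300 probes with the largest rises, 31 held CTAACC, 6 bases of the C-rich telomere repeat, where 3.07 would be expected from all probes tested. Among 130 probes with at least 8 bases of that repeat, the median log2 change was 0.09 in the ratio, 0.12 in Cy3 alone and 0.06 in the reference channel. limma's camera gave an adjusted p of 1.46e-05 for this set, and adjusted p = 0.399 with an estimated correlation. The repeat was picked from the rises in these same arrays, so neither p is independent evidence.

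**Figure D2:**
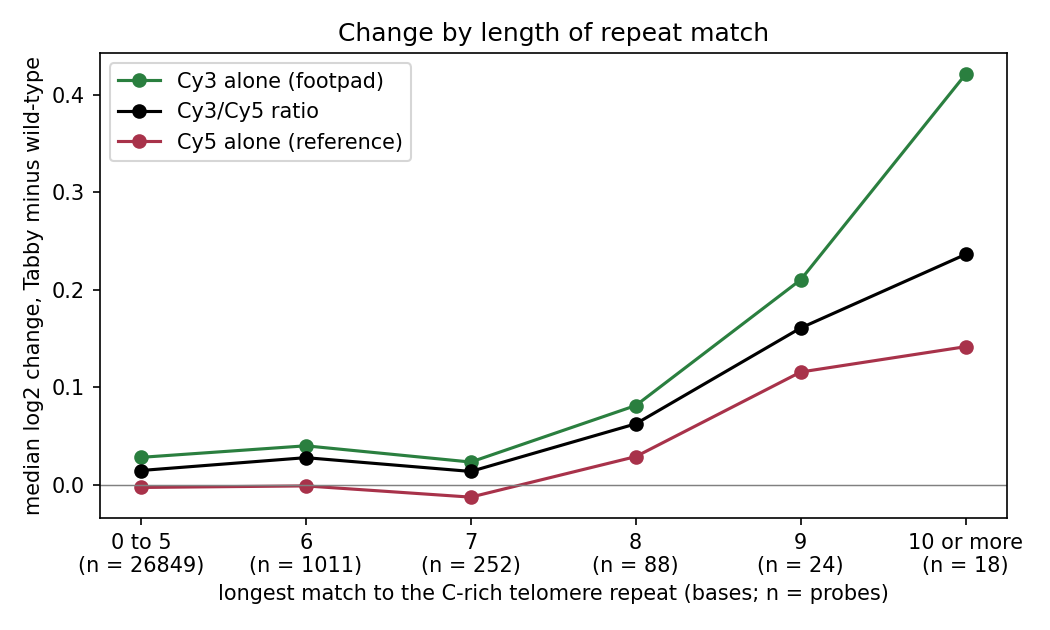
Median log2 change, Tabby minus wild-type (vertical axis), of probes grouped by their longest match to the C-rich telomere repeat in bases (horizontal axis), for the ratio and for each channel alone. At 10 or more bases, over 18 probes, the median is 0.42 in Cy3, 0.24 in the ratio and 0.14 in Cy5.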

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

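Of the tests in this part, those of a shared hybridisation difference, of Cy3 light, of GC content and of wild-type replicate 3 were chosen after related values had been seen, and the repeat itself was picked from the largest rises of these arrays. In the reference channel, which the comparison of genotypes does not use alone, limma called 36 probes between the wild-type and Tabby arrays at an adjusted p under 0.05, all 36 higher on the Tabby arrays. Every array held the same reference RNA, so genotype gives no direct reason for a difference in this channel. The count was 142 without wild-type replicate 3, 483 without wild-type replicate 4, 110 without Tabby replicate 3 and 157 without Tabby replicate 4, and 0 with Agilent's processed signals. Grouping the arrays by replicate number gave 4 calls and 1760 probes at an unadjusted p under 0.05, against 1950 in the real split, and the crossed split gave 0 calls and 628 such probes, so differences between arrays in this channel do not follow genotype alone. Both named probes that were higher in Tabby are among the 36. Cy5 rose by 0.152 per unit of Cy3 at Z00028299-1 but by 0.00912 at Z00026015-1, which is under the bound of 0.0153 given for Cy3 light read as Cy5, so such light is not excluded for Z00026015-1. At least 6 bases of the C-rich telomere repeat occurred in 16 of the 36, against 4.93% of all probes, but 15 of the 36 are also among the 100 largest rises of the ratio, so this is no independent evidence for the repeat.

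Among the 130 probes with at least 8 bases of that repeat, the median change of the footpad to reference ratio was 0.09, and 91 were higher in Tabby, but the groups overlapped: median deviations were 0.0021 and -0.0736 for wild-type replicates 3 and 4, and -0.0032 and 0.0506 for Tabby replicates 3 and 4. Replicate 3 and a lower reference signal are argued against: the change against wild-type replicate 4 alone was 0.0913, and Cy5 was higher, by 0.0596. GC content is argued against too: the 130 probes had a median GC content of 45%, as did the probes outside the 300 largest falls. Removing GC content left 0.0879. Cy3 light read as Cy5 is argued against for the 99 of these probes that rose in Cy3: their median Cy5 rise per unit of Cy3 was 0.199 (lower quartile 0.0511), while the 1st percentile of Cy5 per Cy3 over 1565 bright probes, 0.0153, bounds such light. A hybridisation difference that both channels share stays open, since slide position and genotype cannot be told apart. In Cy5, camera with its preset correlation of 0.01 gave an adjusted p of 3.72e-14. With an estimated correlation, camera gave p = 0.0498 and adjusted p = 0.0996. The repeat was picked from these arrays, so none of these p-values is independent evidence. More labelled G-rich repeat in Tabby footpads, from RNA or residual DNA, and base composition other than GC content may also contribute and stay open: 0 of the control repeats reached the median of the telomere repeat, and those of the same composition had a median of 0.0249 (highest 0.0462), but its choice from these rises largely fixed both outcomes.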

How the results depend on the processing

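The crossed pairing, the removal of GC content and the alternatives for unadjusted counts, the repeat and the reference channel were chosen after seeing the data. The count of 0 probes called by limma became 1 with median centring, 1 with no filter on dim probes, 1 with a trended and robust prior, and 2 on Cy3 alone; Z00036698-1 was each of the single calls and 1 of these 2. With fewer samples, leaving out 1 array gave 0 to 7250. The cause was not tested for the others. With all arrays, probes at an unadjusted p under 0.05 ranged from 1171 to 4841, from unlike numbers of probes tested. The lowest count was 6.62% of 17683 in the authors' value table, and the highest 17.1% of 28242 with the crossed pairing. In the main fit, 34.8% of such probes were higher in Tabby, against 8.45% with median centring and 48.6% with processed signals. With the replicate block 0 probes were called. Deviations of equally numbered samples correlated at -0.276 across probes. With only 2 pairs of samples, that value cannot show whether the numbers pair the samples. The crossed pairing called 1 probe, again Z00036698-1. Z00026015-1 reversed to -0.0631 with processed signals and to -0.0631 in the authors' value table, which holds the same ratio: processed Cy5 was higher by 1.23 in Tabby and Cy3 by 1.16. Z00036698-1 stayed lower under all 17 alternatives, from -2.18 to -1.43. With all arrays, its limma adjusted p ran from 0.00146 with median centring to 0.414 with processed signals. Among these fits it passed only in those named above, of which the crossed pairing was chosen after seeing the data. The repeat's median stayed between 0.05 and 0.12. A slide block was not run, with only 1 slide; testing every probe is already the unit here, and alternatives for gene lists were not run. Dim probes may limit precision, which was not tested. Of all 42006 probes, 64.7% were well above background in Cy3 on all 4 arrays. Testing only such probes, 27169 of them, gave 0 calls.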

Other observations

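The tests in this part, the comparison of splits included, were chosen after related values had been seen. Only the count of probes at an unadjusted p under 0.05 in the real split was chosen before. The 300 probes with the largest falls in Tabby had a median change of -0.77, but -0.30 against wild-type replicate 4 only, so most of their size may come from wild-type replicate 3. A source of direction in that array only is argued against by another set, the 300 largest falls between the replicate 3 arrays. Of these, 97.7% were also lower between the replicate 4 arrays, against 52.0% of all probes, though by a median of -0.21 and not -1.32. Of 300 picked on the replicate 4 arrays, 77% were lower between the replicate 3 arrays, against 43.1% of all probes. Their median was -0.34 in the picking pair and -0.33 in the other. Removing a curve of the change on GC content left -0.76. Over all probes GC content and change correlated only weakly (r = 0.198), so the curve could take little from this median. The 300 had a median GC content of 40%, against 45% for the other probes, and GC content stays open. The polyadenylation signal AATAAA occurred in 7.67% of the 300 and 7.77% of the other probes, but in 15% of the 300 largest rises (2-sided Fisher's exact p = 1.90e-05, probes taken as independent; for all probes with it, camera's adjusted p was 0.00536, and adjusted p = 0.399 with an estimated correlation), so target length and RNA integrity stay open, as do genotype, sex and dissection, untested.

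The real split of the 4 arrays gave 3004 probes at an unadjusted p under 0.05, and the highest of the other splits gave 385. Only 1 of the 3 splits gave as many, and 3 splits are too few for a share under 0.05. The count of 385 is no baseline for chance, because a difference between the real groups widens the spread within groups in the other splits. The share was 10.6% in the real split, 0.574% by replicate number and 1.36% in the crossed split. In the simulation with 2-fold changes, it was 4.81% of the unchanged probes.

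The 2 largest falls, chosen after their values were seen, came from probes that share 19 bases, and both were low mainly in Tabby replicate 3. The first was at -3.71 there and at -0.48 in Tabby replicate 4, and the other at -3.07 and -0.50. By length of match to the telomere repeat, the median change was 0.0146 at 0 to 5 bases, 0.0277 at 6 and 0.0136 at 7. It was 0.0624 at 8 bases over 88 probes, 0.161 at 9 over 24 and 0.24 at 10 or more, where Cy5 alone was at 0.14 over 18 probes. The median was thus not steady up to 7 bases and higher at each longer match. The repeat was picked from the rises in these arrays, so this order is no independent evidence for it.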
